A study of Mus musculus with 52 samples.

How the data were processed

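Liver RNA of 52 mice was measured on 1-colour Agilent mouse arrays, 1 array per mouse according to the series design, so the p-values measure the spread between mice. The groups held 3 mice (KO fasted, LKO fed, LWT fed), 4 (LWT refed, WT fed) or 5 (KO fed, KO refed, LKO fasted, LKO refed, LWT fasted, WT fasted, WT refed). Mice were fed, fasted for 24 h, or fasted for 24 h and refed for 24 h with glucose at 200 g/l in the water. RNA was extracted with TRIzol and labelled with Cy3, per the labels' protocols. Which exons were deleted, and how the lines were bred, is not given in the sources used here.

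The scanner signals are intensity values from Agilent Feature Extraction 10.10.1.1, background-subtracted and detrended on each array and not normalized between arrays, per the file headers. The authors also deposited a value table whose values are on the log2 scale, with limma named among their tools. It held 35516 of the 55681 probes, and every column correlated best with its own array. All columns shared 1 distribution, with medians from 7.32 to 7.34, so they were normalized between arrays. Medians of single probes ran from 7.16 to 7.47, so each probe was centred as well. How the centring and filtering were done is not given in the sources used here.

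The main values were log2 of the processed signal minus the 75th percentile of each array, which ran from 233.5 to 385.98. Control spots and spots with outlier flags were left out, and 51.2% to 68.7% of spots per array were well above background. A probe was kept when it was well above background on at least 3 arrays of at least 1 group, which held for 22623 named probes. Names came from accessions (27235 probes), current symbols (3581), older symbols (565) or the name in the file (1817), and 22483 probes stayed unnamed. The brightest kept probe stood for a gene, which left 16806 genes. Other probes of the same gene went the other way in at least 1 contrast for Rbbp9, Gas5, Trim34a, Apoc3 and Mcm3, among others.

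A model of 12 group means was fitted over all 52 arrays with limma 3.58.1 (lmFit and eBayes), in R 4.3.3, where the R package data.table was at version 1.17.8. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The 22 contrasts compared each deletion with its control line, fasted with fed, refed with fasted, the fasting responses of deletion and control, the whole-body with the liver deletion effect, and LWT with WT. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Where a probe was not well above background on any array of a group, the fold is given as a bound from the lowest signal well above background on each array.

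The contrasts, alternatives, gene lists and rule for named genes were set before the data were examined. Genes named are members of the fixed lists, Ppara, and for each contrast the 10 largest rises and 10 largest falls among called genes. These had to be well above background on every array of at least 1 group, with every array of 1 group on the same side of the mean of the other. Predicted-gene names were left out and fewer genes were printed for space, and some genes are not reported here.

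The 26 lists covered mitochondrial and peroxisomal beta-oxidation, omega-oxidation, ketogenesis, fatty acid uptake, lipid droplets, PPARA-responsive regulators, lipogenesis, cholesterol synthesis, gluconeogenesis, glycolysis, bile acids, acute phase, clock, integrated stress response, chaperones and autophagy. They also covered cell cycle, CAR and PXR targets, NRF2 targets, male-biased and female-biased genes, the growth hormone axis, the urea cycle, lipoproteins and nuclear receptors. The 12 marker lists covered Kupffer, sinusoidal endothelial, stellate, cholangiocyte, lymphocyte, neutrophil, erythroid, adipocyte, acinar, muscle, pericentral and periportal cells. Lists were tested with camera (preset correlation 0.01, and an estimated correlation beside it) and fry. The p of fry tests whether a list moves on balance one way and its Mixed p whether its genes change in either direction, and neither compares the list with other genes.

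The fasting genes of 1 control line, changed by at least 1 log2 unit, were looked up in the deletion of the other line, which shares no arrays, against 10000 random lists matched on signal.

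Alternatives were normexp background correction with an offset of 50, quantile normalization, the authors' value table, no filter and a stricter filter on dim probes, the mean of a gene's probes, slide as a block and replicate number as a block. Others were a fit of only the compared groups, a trended robust prior, each array left out, an estimated correlation for lists, and fasting thresholds of 0.58 and 2. A fit without the genes of chromosome 15 and the contrasts of refed with fed mice were chosen after the data were seen. The 8 slides held 4 to 8 arrays of several groups each.

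The fit was tested on simulated data with 200 of 16806 genes changed. In the LKO against LWT fed design it recovered 53.7%, 67.2% and 92.4% of changes of 0.58, 1 and 2 log2 units, with 7 false among 149 calls. In the KO against WT refed design it recovered 67.2%, 71.6% and 100%. A simulated list of 20 genes raised by 0.5 was called by camera with either correlation and by fry, which also called 1 of the other lists. The simulated genes were drawn independently, so this does not show how often lists of correlated genes are called falsely. The simulated arrays had the same spread in every group and no slide effect. They therefore do not show how often genes are called falsely where groups differ in spread. No pair of arrays was identical, and arrays of a group correlated at 0.9801 to 0.9939.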

Results

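Fasting raised the fat oxidation genes of the liver in both control lines, and most were lower in fasted mice that had lost PPARA. In fasted livers without hepatic PPARA (LKO against LWT, n = 5 and 5), Vnn1, a pantetheinase gene and long-known PPARA target, fell by 37.6-fold (log2 change -5.23 ± 0.30), and the mitochondrial carnitine carrier gene Slc25a20 fell by 4.05-fold (-2.02 ± 0.11). In fasted mice without PPARA anywhere (KO against WT, n = 3 and 5) the same genes changed by -6.19 ± 0.35 and -1.96 ± 0.13. The endoplasmic reticulum chaperone gene Sdf2l1 rose by 1.60 ± 0.26 in LKO and by 4.31 ± 0.30 in KO, and the difference was itself called (2.71 ± 0.39). Values are log2 changes ± standard error, and calls are limma adjusted p under 0.05 over the 16806 genes tested.

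The 52 arrays held liver RNA of 8-week-old C57Bl/6J males, 1 array per mouse. LKO mice lack Ppara in the liver and LWT are their wild-type controls, while KO mice lack it in the whole body and WT are theirs. Each genotype was fed, fasted for 24 h, or fasted for 24 h and refed for 24 h with glucose in the water, and all mice were killed at ZT14. Groups held 3 to 5 arrays, and this number limits the precision of every value below.

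The Ppara signal itself was lower in both deletions in every feeding state. In LKO against LWT it changed by -0.66 ± 0.12 fed, -0.79 ± 0.09 fasted and -1.08 ± 0.10 refed, and in KO against WT by -0.38 ± 0.10, -1.38 ± 0.11 and -0.24 ± 0.09. The fed LKO fall had a limma adjusted p of 0.00033, and over the alternatives from 5.6e-05 to 0.21, the last with only the 6 arrays of the compared groups. The refed KO fall, with an adjusted p of 0.043, lost its call under 4 of the alternatives and when any of 9 of its 10 arrays was left out, its limma adjusted p running from 0.00026 to 0.11. The other Ppara probes gave larger falls in KO, of -0.88 and -0.44 fed and -0.67 and -0.38 refed, and the mean of the probes gave -0.57 and -0.43. Fasting raised Ppara in LWT (0.43 ± 0.11), WT (0.76 ± 0.10) and LKO (0.29 ± 0.11), and KO showed no called change (-0.24 ± 0.11). Signal was left in both deletions, with group means of 5.81 in fasted LKO and 5.47 in fasted KO beside 6.61 and 6.85 in their controls. The labels do not give the deleted exons, so whether the probe lies inside them is not known and the remaining signal does not measure intact PPARA.

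**Figure D1:**
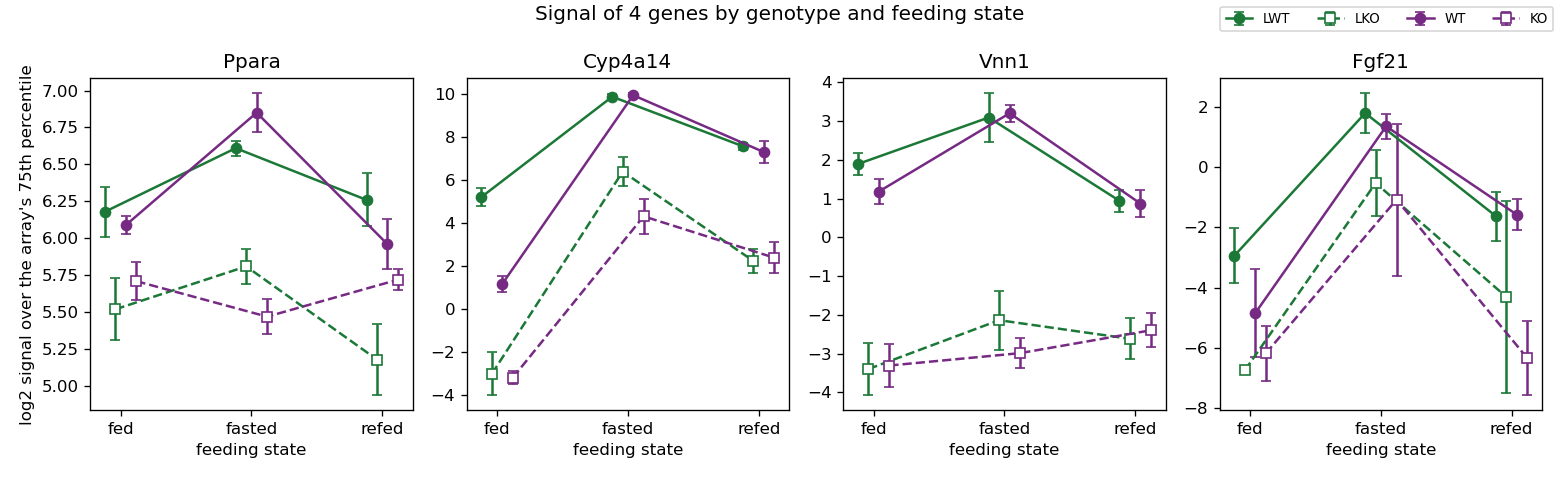
Group means of Ppara, Cyp4a14, Vnn1 and Fgf21 in log2 signal over the 75th percentile of each array (vertical axes) by feeding state (horizontal axes) for LWT, LKO, WT and KO, with bars of 1 standard deviation over the 3 to 5 arrays of a group. Cyp4a14 rose with fasting to 9.87 in LWT and 9.94 in WT but only to 6.38 in LKO and 4.30 in KO.

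Liver deletion in fasted mice lowered the fatty acid oxidation programme nearly gene for gene. Behind Vnn1 came Mtnr1a, a melatonin receptor gene (-4.94 ± 0.49), the complement gene Cfd (-4.14 ± 0.54), Rufy4 (-4.60 ± 0.50, at least 9.44-fold), Slc35f2 (-3.98 ± 0.38, at least 11.4-fold), Serinc2 (-3.91 ± 0.24), the lipid droplet gene Fitm1 (-3.74 ± 0.31), Raet1e (-3.52 ± 0.28) and Cyp4a14, a microsomal fatty acid hydroxylase gene (-3.48 ± 0.32). The largest rises were Gldn (3.81 ± 0.44), Grm8 (3.45 ± 0.39), the Wnt inhibitor gene Wif1 (3.34 ± 0.67), Smpd3 (3.09 ± 0.42), Tafa2 (3.08 ± 0.45) and the stress hormone gene Gdf15 (2.95 ± 0.45). Retsat fell by 3.05 ± 0.14, Plin5 by 3.01 ± 0.29 and the peroxisomal genes Decr2 and Ehhadh by 2.64 ± 0.11 and 2.48 ± 0.13. Fgf21, a fasting hormone of the liver, was lower by 2.32 ± 0.88, a call that was lost without the filter on dim probes.

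The lists were fixed before the data were examined and tested with camera (limma) at a preset correlation of 0.01, and a second p is printed where a call was lost with an estimated correlation. In these, 17 of 18 mitochondrial beta-oxidation genes fell (17 lower adjusted over the list alone, camera adjusted p = 4e-38), including Etfdh (-2.00 ± 0.09), Cpt2 (-1.95 ± 0.07) and Acsl1 (-1.77 ± 0.14), with only Cpt1a not called (-0.09 ± 0.14). Peroxisomal genes fell in 19 of 20 (19 lower adjusted over the list alone, camera adjusted p = 8.4e-31), and Pex13 alone was not called (0.04 ± 0.08). Microsomal omega-oxidation fell in 8 of 9 (8 lower adjusted over the list alone, camera adjusted p = 1.3e-09). Of 6 ketogenesis genes 4 fell (5 lower adjusted over the list alone, camera adjusted p = 7.7e-06), among them Acat1 (-1.35 ± 0.10). Fatty acid uptake and acyl-CoA handling had 12 of 19 lower and 2 higher (2 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.00014), with Acot3 at -1.91 ± 0.38, Fabp1 at -1.80 ± 0.13 and Vldlr the other way at 0.89 ± 0.31. Lipid droplet genes fell in 11 of 17 and rose in 1 (1 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.00014), with G0s2 at -1.49 ± 0.42.

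Other programmes moved the opposite way in fasted LKO. Cholesterol synthesis rose in 15 of 25 genes and fell in 3 (17 higher and 3 lower adjusted over the list alone, camera adjusted p = 1.6e-05, adjusted p = 0.39 with an estimated correlation), with Sqle at 2.35 ± 0.31 and Fdps at 1.80 ± 0.26. Endoplasmic reticulum chaperones rose in 12 of 15 (12 higher adjusted over the list alone, camera adjusted p = 1.2e-07, adjusted p = 0.19 with an estimated correlation), with Sdf2l1 at 1.60 ± 0.26 and Manf at 1.18 ± 0.18. Integrated stress response genes rose in 7 of 15 and fell in 1 (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0072, adjusted p = 0.3 with an estimated correlation), with Atf3 at 2.80 ± 0.43, Nupr1 at 2.77 ± 0.46 and Ddit3 at 2.45 ± 0.27. All 11 Kupffer cell and macrophage markers were higher (11 higher adjusted over the list alone, camera adjusted p = 1.2e-05, adjusted p = 0.3 with an estimated correlation). Marker genes cannot tell a change in the number of a cell type from a change within its cells. CAR and PXR targets rose in 6 of 13 (6 higher adjusted over the list alone, camera adjusted p = 0.0097, adjusted p = 0.3 with an estimated correlation), with Sult1e1 at 2.30 ± 0.48. Female-biased liver genes were higher in 3 of 7 (4 higher adjusted over the list alone, camera adjusted p = 0.04, adjusted p = 0.15 with an estimated correlation).

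In all, 4462 of 16806 genes were called in fasted LKO against LWT, 1926 higher and 2536 lower, and 4511 with slide as a block. The share that was higher was 43.2% here and 61% on the authors' value table, so which direction held the majority depended on normalization. Within the 4 slides that held arrays of both groups, the median change of the mitochondrial beta-oxidation list lay between -1.26 and -1.12, against -1.16 over all arrays. The peroxisomal list lay between -1.40 and -1.18 against -1.30.

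In fed mice, liver deletion already lowered the strongest PPARA targets while few other genes were called (n = 3 and 3). Cyp4a14 fell by 8.23 ± 0.41 (limma adjusted p = 9e-19), Cyp4a10 by 5.91 ± 0.46, Vnn1 by 5.29 ± 0.39, the lysolipid carrier gene Mfsd2a by 5.08 ± 0.51, Mtnr1a by 4.31 ± 0.63, at least 7.68-fold, Fitm1 by 3.87 ± 0.40. Also lower were Cfd by 3.80 ± 0.70, at least 7.38-fold and Serinc2 by 3.52 ± 0.31. Also higher in fed LKO were the metallothionein genes Mt2 (4.10 ± 0.61) and Mt1 (3.29 ± 0.49), the iron-binding Lcn2 (3.88 ± 0.80), Orm3 (3.57 ± 0.57), Saa1 (3.10 ± 0.73) and Moxd1 (6.19 ± 1.30). Gldn, a cell adhesion gene, rose by 4.08 ± 0.57, at least 11.9-fold. Fgf21 was not called (-3.81 ± 1.1, at least 2.98-fold).

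Mitochondrial beta-oxidation fell in 14 of 18 genes in fed LKO (17 lower adjusted over the list alone, camera adjusted p = 4.7e-58), with Slc25a20 at -2.08 ± 0.14 and Acadl at -1.32 ± 0.12. Peroxisomal genes fell in 14 of 20 (15 lower adjusted over the list alone, camera adjusted p = 2.8e-40), with Abcd2 at -3.03 ± 0.43, at least 1.81-fold. Omega-oxidation genes fell in 5 of 9 (6 lower adjusted over the list alone, camera adjusted p = 2.6e-24). Ketogenesis fell in 3 of 6 (1 higher and 4 lower adjusted over the list alone, camera adjusted p = 8.1e-07). PPARA-responsive regulators and hepatokines fell in 7 of 16 and rose in 1 (2 higher and 10 lower adjusted over the list alone, camera adjusted p = 1.2e-10), with Klf11 at -1.74 ± 0.37, at least 2.47-fold, Retsat at -1.87 ± 0.18 and the pyruvate dehydrogenase kinase gene Pdk4 the other way at 1.61 ± 0.42. Acute phase genes rose in 9 of 23 (13 higher adjusted over the list alone, camera adjusted p = 2.8e-16), with Apcs at 1.42 ± 0.28. Neutrophil markers had a median of 1.17 with 0 of 6 called (0 of either direction adjusted over the list alone, camera adjusted p = 0.011, adjusted p = 0.16 with an estimated correlation). Stellate cell markers fell in 3 of 11 (4 lower adjusted over the list alone, camera adjusted p = 0.002, adjusted p = 0.2 with an estimated correlation). Sinusoidal endothelial markers fell in 1 of 10 (4 lower adjusted over the list alone, camera adjusted p = 0.00028, adjusted p = 0.16 with an estimated correlation).

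The fed LKO contrast called 501 genes, 187 higher and 314 lower, and 519 with slide as a block. No slide held arrays of both groups, so no comparison within a slide supports this contrast, and the share that was higher was 37.3% here and 27.4% with the block. Leaving out LWT fed replicate 2 gave 301, LWT fed replicate 3 gave 315 and LKO fed replicate 3 gave 320. The authors' value table gave 1033, and a fit of only the compared groups gave 82, where Mfsd2a, Fitm1, Cfd, Moxd1, Lcn2, Orm3, Saa1, Mt1, Apcs and Klf11 lost their calls.

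In refed mice, fat oxidation genes were lower with the liver deletion although refeeding had already lowered them in the controls (n = 5 and 4). Cyp4a14 was lower by 5.34 ± 0.34 (limma adjusted p = 1.7e-15), Rufy4 by 4.13 ± 0.53, at least 4.78-fold, Mtnr1a by 3.72 ± 0.52, Vnn1 by 3.56 ± 0.32, Fitm1 by 3.53 ± 0.33, Mfsd2a by 3.47 ± 0.42, Ctcflos by 3.33 ± 0.35 and Retsat by 2.72 ± 0.15. Gldn was higher by 5.89 ± 0.47, Moxd1 by 3.59 ± 1.1, Tafa2 by 3.54 ± 0.48, Derl3 by 3.06 ± 0.41, the bile acid exporter gene Slc51b by 2.27 ± 0.56, Pdk4 by 2.06 ± 0.35 and Apoa4 by 1.49 ± 0.30. Mitochondrial beta-oxidation was lower in 16 of 18 (16 lower adjusted over the list alone, camera adjusted p = 2.7e-32), with Etfdh at -1.22 ± 0.09. Peroxisomal genes were lower in 14 of 20 and higher in 1 (1 higher and 16 lower adjusted over the list alone, camera adjusted p = 2.9e-16). Omega-oxidation genes were lower in 8 of 9 (9 lower adjusted over the list alone, camera adjusted p = 3.1e-18). Urea cycle and amino acid catabolism genes were lower in 10 of 23 (17 lower adjusted over the list alone, camera adjusted p = 3.2e-09, adjusted p = 0.27 with an estimated correlation), with Sds at -0.81 ± 0.23. Periportal hepatocyte markers were lower in 6 of 11 (9 lower adjusted over the list alone, camera adjusted p = 0.00048, adjusted p = 0.21 with an estimated correlation). Kupffer cell markers were higher in 6 of 11 (10 higher adjusted over the list alone, camera adjusted p = 1.1e-07, adjusted p = 0.21 with an estimated correlation). Neutrophil markers were higher in 1 of 6, but the list was not called (2 higher adjusted over the list alone, camera adjusted p = 0.22). Of the adipocyte markers 3 of 7 were lower (3 lower adjusted over the list alone, camera adjusted p = 0.021, adjusted p = 0.28 with an estimated correlation). The markers include Cfd, lower in both deletions in every state, and the gluconeogenesis gene Pck1, so the fall need not come from a trace of fat tissue. LKO refed replicate 1 stood apart low for the urea cycle and adipocyte lists.

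Refed LKO against LWT called 1747 genes, 756 higher and 991 lower, and 2117 with slide as a block. The count was 824 without LWT refed replicate 4, 999 without LWT refed replicate 5 and 372 in a fit of only the compared groups. The share of called genes that were higher was 43.3% here and 67.5% on the authors' value table. Within the 3 slides that held both groups, the beta-oxidation list median lay between -0.61 and -0.41, against -0.58 over all arrays, while the lipogenesis list lay between -0.50 and 0.50 and the Kupffer cell list between -0.10 and 1.17, so neither had a stable direction within slides.

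Whole-body deletion in fasted mice lowered fat oxidation genes and raised chaperone genes (n = 3 and 5). The calls of the stress, glucose and amino acid lists were lost with an estimated correlation. Beside Vnn1, Fitm1 (-6.48 ± 0.36), Serinc2 (-5.38 ± 0.27), Cyp4a14 (-5.64 ± 0.37) and Retsat (-4.90 ± 0.16) fell. Also lower were the bile acid enzyme gene Cyp8b1 (-5.73 ± 0.29), Acot3 (-4.50 ± 0.44) and Fabp1, the liver fatty acid binding protein gene (-3.94 ± 0.15). The secretory-cell transcription factor gene Bhlha15 rose by 7.52 ± 0.58, at least 65.9-fold, Derl3, an endoplasmic reticulum degradation gene, by 6.29 ± 0.45. Sult1e1 rose by 6.37 ± 0.55, the drug-metabolizing Cyp2b9 and Cyp2b10 by 5.79 ± 0.92 and 5.68 ± 1.1, Lcn2 by 5.77 ± 0.72 and Gdpd3 by 7.42 ± 1.1. The probe sequences were not compared, so near-identical paralogs such as Cyp2b9 and Cyp2b10, or Cyp4a10, Cyp4a31 and Cyp4a32, may share signal here. Counts that hold several of them may count the same signal repeatedly. Camk2b (-7.21 ± 0.40, at least 67.3-fold) and Tmem25 (-6.40 ± 0.21) fell in the other feeding states as well and are among the KO genes treated below, whose cause stays open. Trim12a (-7.92 ± 0.14, at least 63.5-fold) and Sugct (-5.84 ± 0.12) also fell in all states, and Sugct was lower in LKO too.

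All 18 mitochondrial beta-oxidation genes fell in fasted KO (18 lower adjusted over the list alone, camera adjusted p = 3.4e-22), with Eci1 at -2.15 ± 0.07 and Etfdh at -2.13 ± 0.10. Peroxisomal genes fell in 18 of 20 (19 lower adjusted over the list alone, camera adjusted p = 2.6e-17), with Abcd2 at -3.68 ± 0.38, at least 3.41-fold. All 9 omega-oxidation genes fell (9 lower adjusted over the list alone, camera adjusted p = 4e-08). Ketogenesis fell in 4 of 6 and rose in 1 (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0046, adjusted p = 0.15 with an estimated correlation). Fatty acid uptake fell in 15 of 19 and rose in 2 (2 higher and 15 lower adjusted over the list alone, camera adjusted p = 0.00027). Lipid droplet genes fell in 9 of 17 and rose in 1 (1 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.011, adjusted p = 0.15 with an estimated correlation). Gluconeogenesis genes fell in 14 of 20 (15 lower adjusted over the list alone, camera adjusted p = 0.00019, adjusted p = 0.2 with an estimated correlation), with Ppargc1a at -2.82 ± 0.32 and G6pc at -2.50 ± 0.32. Urea cycle and amino acid genes fell in 19 of 23 (19 lower adjusted over the list alone, camera adjusted p = 7.2e-07, adjusted p = 0.31 with an estimated correlation), with Cps1 at -1.19 ± 0.18 and Sds at -1.92 ± 0.26. Periportal markers fell in 9 of 11 (10 lower adjusted over the list alone, camera adjusted p = 0.00032, adjusted p = 0.15 with an estimated correlation). Growth hormone and IGF axis genes fell in 5 of 10 and rose in 1 (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.19), with Igfals at -3.29 ± 0.22. Lipoprotein and HDL genes fell in 10 of 16 and rose in 1 (1 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.041, adjusted p = 0.4 with an estimated correlation).

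Several lists rose in fasted KO. All 15 endoplasmic reticulum chaperones rose (15 higher adjusted over the list alone, camera adjusted p = 8.9e-16), with Hyou1 at 2.82 ± 0.22, Manf at 2.91 ± 0.20, Creld2 at 3.07 ± 0.35 and Hspa5 at 1.70 ± 0.16. Integrated stress response genes rose in 10 of 15 and fell in 1 (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00027, adjusted p = 0.15 with an estimated correlation), with Psat1 at 4.63 ± 0.57, Nupr1 at 4.58 ± 0.53, Mthfd2 at 4.05 ± 0.50, at least 13.4-fold and Chac1 at 3.41 ± 0.42. Acute phase genes rose in 13 of 23 and fell in 1 (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.2e-05, adjusted p = 0.24 with an estimated correlation), with Saa2 at 4.72 ± 0.68, Orm3 at 4.36 ± 0.51 and Apcs at 2.72 ± 0.25. Neutrophil markers had a median of 2.09 with 4 of 6 higher, but the list was not called (4 higher adjusted over the list alone, camera adjusted p = 0.068). CAR and PXR targets rose in 9 of 13 and fell in 2 (9 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0024, adjusted p = 0.19 with an estimated correlation), with Gstm2 at 2.52 ± 0.22. Cholesterol synthesis went the other way from fasted LKO, falling in 15 of 25 and rising in 1 (1 higher and 16 lower adjusted over the list alone, camera adjusted p = 0.00053, adjusted p = 0.45 with an estimated correlation), with Sc5d at -1.93 ± 0.15. Lipogenesis fell in 12 of 27 and rose in 2 (2 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.03, adjusted p = 0.5 with an estimated correlation), with Fads2 at -3.43 ± 0.21. Glycolysis and glycogen genes fell in 11 of 17 and rose in 1 (1 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.0085, adjusted p = 0.39 with an estimated correlation). Bile acid genes were split, 3 higher and 6 lower of 17 (3 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.56), and fry called them changed in either direction (Mixed adjusted p = 3.3e-15), with Cyp7a1 at -2.63 ± 0.59.

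Smaller lists in fasted KO were mostly undecided. Lymphocyte markers were lower in 5 of 9 (6 lower adjusted over the list alone, camera adjusted p = 0.1). Male-biased liver genes were lower in 6 of 12 and higher in 2 (2 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.1). Nuclear receptors split into 4 higher and 4 lower of 15 (4 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.91), with Pparg at 1.84 ± 0.22. Circadian clock genes were lower in 6 of 16 and higher in 3 (3 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.97), with Arntl at -1.84 ± 0.63. Pancreatic acinar markers had 1 higher and 0 lower of 5 (1 higher adjusted over the list alone, camera adjusted p = 0.34). Muscle markers, the other foreign tissue, had 0 higher and 1 lower of 4 (1 lower adjusted over the list alone, camera adjusted p = 0.61).

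Fasted KO against WT called 7614 genes, 3352 higher and 4262 lower, and 7551 with slide as a block. The share that was higher was 44% here, 59.2% on the authors' value table and 52.9% after quantile normalization, so the majority direction depended on normalization. A single slide held both groups, and there the chaperone list median was 1.75 against 1.60 over all arrays and the beta-oxidation list -1.48 against -1.51.

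In fed mice, whole-body deletion lowered the core PPARA targets (n = 5 and 4). Cyp4a14 fell by 4.37 ± 0.34 (limma adjusted p = 6.3e-14), Vnn1 by 4.49 ± 0.32, Fitm1 by 4.37 ± 0.33, Abcd2 by 3.17 ± 0.35, at least 1.97-fold, Plin5 by 2.47 ± 0.31 and Slc25a20 by 2.04 ± 0.12, and Serpina12, an insulin-sensitizing secreted protein gene, by 5.41 ± 0.76, at least 11.7-fold. Apoa4 rose by 3.90 ± 0.30, the lipoprotein receptor gene Vldlr by 3.17 ± 0.33, Moxd1 by 5.70 ± 1.1, Tafa2 by 5.01 ± 0.48 and Orm3 by 3.19 ± 0.47. The Cyp4a14 call was lost on the authors' value table. Rbbp9 (-8.47 ± 0.85), Gas5 (-5.62 ± 0.30) and Trim34a (-4.91 ± 0.20) also fell, but another probe of Rbbp9 went the other way here, and other probes of Gas5 and Trim34a did so in another feeding state.

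By list, beta-oxidation fell in 11 of 18 and rose in 2 (2 higher and 13 lower adjusted over the list alone, camera adjusted p = 2.2e-09, adjusted p = 0.18 with an estimated correlation), with Acadm among those that rose (0.31 ± 0.08). Peroxisomal genes fell in 8 of 20 and rose in 1 (2 higher and 8 lower adjusted over the list alone, camera adjusted p = 3.3e-06, adjusted p = 0.17 with an estimated correlation). Omega-oxidation fell in 5 of 9 (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 2e-06, adjusted p = 0.17 with an estimated correlation). Kupffer cell markers were lower in 10 of 11 (10 lower adjusted over the list alone, camera adjusted p = 2.3e-05, adjusted p = 0.44 with an estimated correlation), the opposite of fasted and refed LKO. Cholangiocyte markers were lower in 4 of 7 (4 lower adjusted over the list alone, camera adjusted p = 0.027, adjusted p = 0.44 with an estimated correlation). Pericentral hepatocyte markers were higher in 4 of 12 (6 higher adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.44 with an estimated correlation). Nuclear receptors rose in 7 of 15 and fell in 1 (8 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.023, adjusted p = 0.44 with an estimated correlation). In all 4317 genes were called, 2436 higher and 1881 lower, and 4497 with slide as a block. The share that was higher was 56.4% here and 40.2% on the authors' value table. Within the 3 slides that held both groups, the beta-oxidation list median lay between -0.40 and -0.27 and the Kupffer list between -1.08 and -0.34, against -0.39 and -0.66 over all arrays.

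In refed mice, whole-body deletion left fat and cholesterol synthesis genes lower than in WT (n = 5 and 5). Refed LWT also differed from refed WT, with medians of -0.33 for lipogenesis, -0.56 for cholesterol synthesis, 0.63 for gluconeogenesis and 0.3 for autophagy. In KO the medians were -0.99, -0.48, 0.31 and 0.32. Only for lipogenesis did the KO shift clearly exceed this line difference, so the others may be a trait of the refed WT group. Lipogenesis genes were lower in 16 of 27 and higher in 1 (1 higher and 17 lower adjusted over the list alone, camera adjusted p = 2.5e-07, adjusted p = 0.32 with an estimated correlation), with Pnpla5 at -2.94 ± 0.61, Pnpla3 at -2.30 ± 0.72, Gpam at -1.62 ± 0.26, Srebf1 at -1.57 ± 0.22, Scd1 at -1.56 ± 0.26 and Fasn at -1.23 ± 0.32. Cholesterol synthesis genes were lower in 12 of 25 (12 lower adjusted over the list alone, camera adjusted p = 0.0013, adjusted p = 0.55 with an estimated correlation). Fgf21 was lower by 4.76 ± 0.88, Cyp4a14 by 4.92 ± 0.32 (limma adjusted p = 2e-16), Abcd2 by 3.53 ± 0.33, at least 3.58-fold, Vnn1 by 3.27 ± 0.30 and Plin4 by 2.66 ± 0.43. Cyp2c39 was higher by 4.21 ± 0.25, Vldlr by 3.02 ± 0.31, Sult1e1 by 2.77 ± 0.48, the insulin signalling gene Irs2 by 1.70 ± 0.29 and Acot1 by 1.79 ± 0.36. Beta-oxidation was split into 7 lower and 5 higher of 18 (7 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.11), and fry called it changed in either direction (Mixed adjusted p = 2.3e-14), with Cpt2 at -0.98 ± 0.07 against Acadm at 0.72 ± 0.08. Gluconeogenesis genes were higher in 12 of 20 and lower in 1 (13 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.011, adjusted p = 0.44 with an estimated correlation), with Pck1 at 1.23 ± 0.26. CAR and PXR targets were higher in 8 of 13 and lower in 1 (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.011, adjusted p = 0.33 with an estimated correlation). Autophagy and lysosome genes were higher in 10 of 18 (11 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0068, adjusted p = 0.33 with an estimated correlation). The contrast called 5123 genes, 3043 higher and 2080 lower, and 5066 with slide as a block. Within the 4 slides that held both groups, the lipogenesis list median lay between -1.17 and -0.49 against -0.99 over all arrays.

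**Figure D2:**
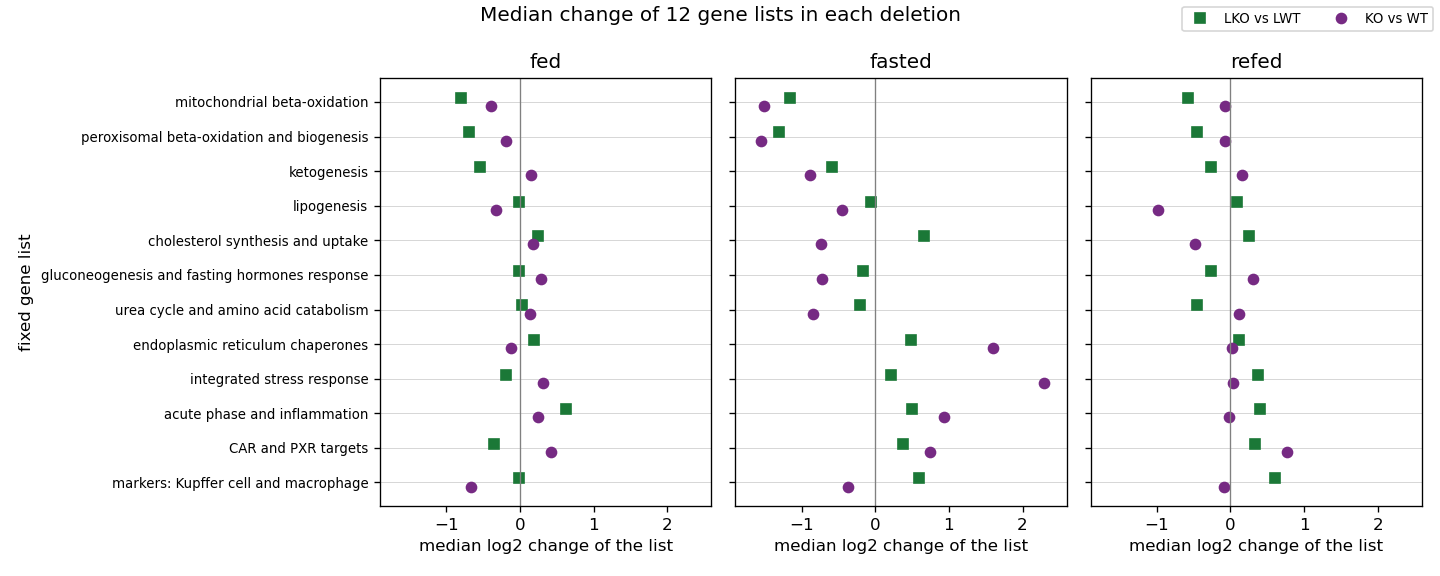
Median log2 change (horizontal axes) of 12 fixed gene lists (vertical axis) in LKO against LWT (squares) and KO against WT (circles), with 1 panel per feeding state. Beta-oxidation medians were -1.16 and -1.51 in the fasted state, where the chaperone medians were 0.48 and 1.60.

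Fasting in the LWT control line raised fat oxidation genes and lowered fat synthesis, cholesterol and cell cycle genes (n = 5 and 3). Fgf21 rose by 4.72 ± 1.00, Cyp4a14 by 4.66 ± 0.37 (limma adjusted p = 1e-12), Msmp by 3.84 ± 0.38, the lipid droplet gene Cidec by 3.31 ± 0.49, Acot3 by 3.13 ± 0.44 and Pdk4 by 2.63 ± 0.38. Falls were seen in Hsd3b5 (-5.55 ± 0.42), the retinoic acid hydroxylase gene Cyp26a1 (-5.17 ± 0.61), Fabp5 (-4.40 ± 0.36), Thrsp (-4.11 ± 0.29) and Fasn (-3.54 ± 0.37). Beta-oxidation rose in 16 of 18 (17 higher adjusted over the list alone, camera adjusted p = 5.2e-17) and peroxisomal genes in 15 of 20 (17 higher adjusted over the list alone, camera adjusted p = 7.2e-13). PPARA-responsive regulators rose in 10 of 16 (10 higher adjusted over the list alone, camera adjusted p = 3.3e-06). Lipogenesis fell in 19 of 27 (21 lower adjusted over the list alone, camera adjusted p = 3.7e-17). Cholesterol synthesis fell in 20 of 25 (20 lower adjusted over the list alone, camera adjusted p = 4.4e-15, adjusted p = 0.075 with an estimated correlation). Cell cycle genes fell in 12 of 18 (13 lower adjusted over the list alone, camera adjusted p = 2.3e-08, adjusted p = 0.075 with an estimated correlation), with Mcm5 at -3.03 ± 0.35. Urea cycle genes rose in 16 of 23 (17 higher adjusted over the list alone, camera adjusted p = 8.7e-09, adjusted p = 0.2 with an estimated correlation).

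The WT line gave a similar programme (n = 5 and 4). Cyp4a14 rose by 8.78 ± 0.34 (limma adjusted p = 3.4e-23), Fgf21 by 6.19 ± 0.93, the glycogen-targeting gene Ppp1r3g by 5.95 ± 0.80, Igfbp1 by 5.43 ± 0.59 and Cidec by 5.18 ± 0.45. Falls were seen in Hsd3b5 (-7.38 ± 0.38), Bhlha15 (-6.34 ± 0.54, at least 29.1-fold) and Cyp2c70 (-5.37 ± 0.22). All 18 beta-oxidation genes rose (18 higher adjusted over the list alone, camera adjusted p = 1.5e-17) and 18 of 20 peroxisomal genes (18 higher adjusted over the list alone, camera adjusted p = 3.2e-17). Gluconeogenesis genes rose in 16 of 20 (17 higher adjusted over the list alone, camera adjusted p = 4.8e-09), with Ppargc1a at 2.41 ± 0.29. Endoplasmic reticulum chaperones fell in 14 of 15 (14 lower adjusted over the list alone, camera adjusted p = 4.7e-10, adjusted p = 0.089 with an estimated correlation), with Hyou1 at -1.79 ± 0.20. The counts were 4138 genes in LWT (2024 higher, 2114 lower) and 6571 in WT (3442 higher, 3129 lower), and 3562 and 6805 with slide as a block. The share that was higher in WT was 52.4% here, 43.3% on the authors' value table and 45.7% after quantile normalization. No slide held both fed and fasted LWT arrays.

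Without hepatic PPARA, fasting still raised the strongest targets from a lower base but raised fewer beta-oxidation genes than in LWT (n = 5 and 3). In LKO, Cyp4a14 rose by 9.41 ± 0.37 (limma adjusted p = 6.3e-23), Fgf21 by 6.21 ± 1.00, at least 15.8-fold, Ppp1r3g by 5.31 ± 0.87 and Atf3 by 3.43 ± 0.49. Serpina9 fell by 5.83 ± 0.58, Srebf1 by 4.29 ± 0.25 and Saa1 by 4.02 ± 0.66. Mean Cyp4a14 signals were -3.03 fed and 6.38 fasted in LKO beside 5.20 and 9.87 in LWT. Beta-oxidation rose in 7 of 18 and fell in 1 (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.011, adjusted p = 0.49 with an estimated correlation), with Acadl at 1.50 ± 0.11 and Hadha not called (-0.12 ± 0.09). PPARA-responsive regulators rose in 13 of 16 (13 higher adjusted over the list alone, camera adjusted p = 2.2e-07). Female-biased genes rose in 5 of 7 (5 higher adjusted over the list alone, camera adjusted p = 7e-04). NRF2 targets rose in 8 of 11 (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.011, adjusted p = 0.4 with an estimated correlation), with Nqo1 at 1.62 ± 0.31. Acute phase genes fell in 15 of 23 and rose in 4 (5 higher and 15 lower adjusted over the list alone, camera adjusted p = 0.00051, adjusted p = 0.4 with an estimated correlation). Neutrophil markers fell in 3 of 6 (5 lower adjusted over the list alone, camera adjusted p = 0.048, adjusted p = 0.38 with an estimated correlation), with a median of -1.72. The LKO fasting contrast called 5625 genes, 2728 higher and 2897 lower, and 5943 with slide as a block. The share that was higher was 48.5% here and 52.4% on the authors' value table.

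In KO, fasting raised most chaperone genes, and more beta-oxidation genes fell than rose (n = 3 and 5). Cyp4a14 rose by 7.51 ± 0.37 (limma adjusted p = 3.8e-20), Sult1e1 by 6.83 ± 0.55, Cyp2b9 by 5.40 ± 0.92, Fgf21 by 5.10 ± 1.00, at least 9.94-fold, Gdf15 by 3.92 ± 0.52 and Psat1 by 3.50 ± 0.57. The carbonic anhydrase gene Car3 (-6.94 ± 0.38), Prok1 (-5.77 ± 0.47), Keg1 (-5.08 ± 0.24), Cyp7a1 (-4.88 ± 0.59), Igfals (-4.56 ± 0.22) and Fabp1 (-4.19 ± 0.15) fell. All 6 ketogenesis genes fell (6 lower adjusted over the list alone, camera adjusted p = 0.037, adjusted p = 0.27 with an estimated correlation). Beta-oxidation fell in 9 of 18 and rose in 3 (3 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.38). All 25 cholesterol synthesis genes fell (25 lower adjusted over the list alone, camera adjusted p = 2.4e-18, adjusted p = 0.13 with an estimated correlation). So did 15 of 17 glycolysis genes (15 lower adjusted over the list alone, camera adjusted p = 1.4e-07, adjusted p = 0.14 with an estimated correlation). Male-biased genes fell in 10 of 12 (10 lower adjusted over the list alone, camera adjusted p = 1.5e-06, adjusted p = 0.16 with an estimated correlation). Chaperones rose in 12 of 15 (13 higher adjusted over the list alone, camera adjusted p = 1.4e-07, adjusted p = 0.22 with an estimated correlation). Called genes numbered 7193, 3056 higher and 4137 lower, and 7371 with slide as a block. The share that was higher was 42.5% here and 61.8% on the authors' value table.

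The difference between fasting responses put numbers on what each deletion changed. In LKO minus LWT, Cyp4a14 rose by 4.75 ± 0.52 more in LKO (limma adjusted p = 1.1e-07), Atf3 by 3.14 ± 0.70 and Nupr1 by 3.03 ± 0.75, while the difference was negative for Mt2 (-4.07 ± 0.77) and G0s2 (-2.77 ± 0.68), which rose in LWT only. It was also negative for 7 of 18 beta-oxidation genes and positive for 1 (1 higher and 13 lower adjusted over the list alone, camera adjusted p = 6.3e-08, adjusted p = 0.2 with an estimated correlation). In LKO minus LWT 1002 genes differed, and 657 without LWT fed replicate 2, 639 in a fit of only the compared groups. In KO minus WT the difference was positive for Bhlha15 (7.66 ± 0.79), Psat1 (6.20 ± 0.78) and Sdf2l1 (4.69 ± 0.40), which fell on fasting in WT. It was negative for Acot3 (-5.78 ± 0.60) and Cyp8b1 (-5.63 ± 0.40), which rose in WT and fell in KO, and for Fabp1 (-4.01 ± 0.20), which fell in KO. It was negative for 16 of 18 beta-oxidation genes (16 lower adjusted over the list alone, camera adjusted p = 3.4e-15) and positive for 14 of 15 chaperones (15 higher adjusted over the list alone, camera adjusted p = 1e-19). For fatty acid uptake it was negative in 12 of 19 and positive in 2 (2 higher and 12 lower adjusted over the list alone, camera adjusted p = 1.6e-05). In KO minus WT 5133 genes differed, and the share that was higher was 38.9% here, 29% with normexp and 65.3% on the authors' value table. Each difference also holds any fed difference between deletion and control, such as the low Cyp4a14 and the high Mt2 of fed LKO.

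Refeeding with glucose raised fat synthesis genes in every genotype. In LWT (n = 4 and 5) Pnpla3 rose by 6.62 ± 0.76, Fasn by 6.09 ± 0.34 (limma adjusted p = 3.3e-18), the glucose transporter gene Slc2a4 by 6.05 ± 0.38, Elovl6 by 5.18 ± 0.32 and Acly by 4.10 ± 0.20. In WT (n = 5 and 5) Pnpla5 rose by 7.97 ± 0.61, at least 64.8-fold, Fasn by 7.08 ± 0.32 and Fabp5 by 6.20 ± 0.31. Acot1 fell by 4.23 ± 0.36 and 5.76 ± 0.36 and Cidec by 3.92 ± 0.45 and 5.57 ± 0.42. Lipogenesis rose in 23 of 27 genes in LWT (24 higher adjusted over the list alone, camera adjusted p = 2.4e-28) and 23 in WT (23 higher adjusted over the list alone, camera adjusted p = 4.9e-23). It rose in 25 in LKO (25 higher adjusted over the list alone, camera adjusted p = 2.6e-23) and in all 27 in KO (27 higher adjusted over the list alone, camera adjusted p = 4.4e-24). Cholesterol synthesis rose in 20 of 25 in LWT (20 higher adjusted over the list alone, camera adjusted p = 1.1e-16, adjusted p = 0.056 with an estimated correlation) and in all 25 in KO (25 higher adjusted over the list alone, camera adjusted p = 7.2e-24). Urea cycle genes fell in 22 of 23 in WT (22 lower adjusted over the list alone, camera adjusted p = 5.4e-13, adjusted p = 0.12 with an estimated correlation), with Cth at -2.84 ± 0.18.

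Beta-oxidation as a list fell on refeeding in the control lines and not in the deletions, though this difference was not itself tested. It fell in 15 of 18 genes in LWT (15 lower adjusted over the list alone, camera adjusted p = 1.7e-13) and in all 18 in WT (18 lower adjusted over the list alone, camera adjusted p = 6.5e-15). LKO had 5 lower and 4 higher (4 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.45). In KO 4 were lower and 12 higher (12 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.036, adjusted p = 0.83 with an estimated correlation). Hadha, for example, changed by -0.46 ± 0.08 in LWT and -0.63 ± 0.07 in WT but rose by 0.49 ± 0.07 in LKO and 1.17 ± 0.09 in KO. In LKO (n = 5 and 5) Thrsp rose by 5.56 ± 0.25. In KO (n = 5 and 3) Car3 rose by 6.89 ± 0.38, Nsdhl by 5.09 ± 0.27 and Fabp1 by 4.04 ± 0.15, and Sult1e1 fell by 5.82 ± 0.55 and Gdf15 by 4.24 ± 0.52. Chaperones fell in 12 of 15 in KO (13 lower adjusted over the list alone, camera adjusted p = 9.2e-10, adjusted p = 0.23 with an estimated correlation). Refeeding called 6334 genes in LWT, 8712 in WT, 7967 in LKO and 7148 in KO, and 6352, 8775, 8068 and 7099 with slide as a block.

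The whole-body and liver deletion effects differed in every feeding state. In the fasted state Psat1 (4.90 ± 0.76), Lcn2 (4.86 ± 0.95), Cyp2b9 (5.98 ± 1.20) and Bhlha15 (4.68 ± 0.77) had a higher change with the whole-body deletion, and Cyp8b1 (-4.54 ± 0.39) a lower one. Cholesterol synthesis was lower in 23 of 25 genes (24 lower adjusted over the list alone, camera adjusted p = 7e-15, adjusted p = 0.27 with an estimated correlation). Chaperones were higher in 13 of 15 (13 higher adjusted over the list alone, camera adjusted p = 6.8e-14, adjusted p = 0.26 with an estimated correlation). Kupffer cell markers were lower in 8 of 11 (10 lower adjusted over the list alone, camera adjusted p = 3.4e-05, adjusted p = 0.42 with an estimated correlation), and beta-oxidation in 7 of 18 (7 lower adjusted over the list alone, camera adjusted p = 0.01, adjusted p = 0.5 with an estimated correlation). In the fed state the difference for beta-oxidation was positive in 8 of 18 (12 higher adjusted over the list alone, camera adjusted p = 4.6e-06, adjusted p = 0.24 with an estimated correlation). In the refed state it was positive in 17 of 18 (18 higher adjusted over the list alone, camera adjusted p = 1.8e-09, adjusted p = 0.24 with an estimated correlation). There lipogenesis was lower in 15 of 27 and higher in 1 (1 higher and 16 lower adjusted over the list alone, camera adjusted p = 5.2e-07, adjusted p = 0.24 with an estimated correlation). The differences called 1611 genes fed, 3553 fasted and 4194 refed, and the fasted count was 1617 on the authors' value table. The breeding of the lines is not given in the sources used here, and a difference between the deletions holds line differences as well as the site of deletion.

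Genes that responded to fasting in one control line were looked up in the deletion of the other, which shares no array with them. Of the 664 genes that rose in fasted WT by at least 1 log2 unit, Vnn1 and Acot3 among them, 203 (30.6%) were lower and 62 (9.34%) higher in fasted LKO against LWT. Their median was -0.07, at percentile 5.87 of 10000 random lists matched for signal, and with thresholds of 0.58 and 2 it was -0.08 and -0.35, both at percentile 0. Of all 16806 genes 2536 were lower and 1926 higher in this contrast. The 673 that fell had a median of 0.16 at percentile 100, with 180 (26.7%) higher and 64 (9.51%) lower. Of the 352 genes that rose in fasted LWT, 150 (42.6%) were lower and 48 (13.6%) higher in fasted KO against WT, where 4262 of all genes were lower and 3352 higher, and their median was -0.49 at percentile 0. The 402 that fell had a median of 0.27 at percentile 100, with 153 (38.1%) higher and 71 (17.7%) lower. Genes are not independent replicates.

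By correlation and number of shared calls the deletions shared most in fasted mice, while as a ratio to chance the shared falls were highest in fed mice. Across genes, which are not independent replicates, the log2 changes of KO against WT and LKO against LWT had a Pearson correlation of 0.277 fed, 0.529 fasted and 0.069 refed, and a Spearman correlation of 0.137, 0.492 and -0.053. Genes lower in both numbered 158 fed, 1781 fasted and 205 refed, where 35.1, 643 and 123 would arise if calls were independent, and genes higher in both 84, 1144 and 177 against 27.1, 384 and 137. Opposite calls numbered 28, 208 and 372, so in refed livers opposite calls were nearly as many as matching ones. Chance counts were computed for matching calls only, so the shared calls of refed livers do not by themselves show a shared direction. In every feeding state and both deletions 84 genes were lower, among them Vnn1, Cyp4a14, Cyp4a10, Slc25a20, Cpt2, Etfdh, Ech1, Decr2, Hsd17b4, Plin5, Fitm1, Fitm2, Retsat, Mfsd2a and Serinc2. The 20 that were higher in all held Ctsl, a lysosomal protease gene, Tafa2, Smpd3 and Grm8.

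The control lines differed from each other before any deletion. In fed mice (LWT against WT, n = 3 and 4) Cyp4a14 was higher by 4.05 ± 0.39 (limma adjusted p = 5.2e-09), Cyp4a10 by 2.32 ± 0.43, the asparagine synthetase gene Asns by 3.49 ± 0.69 and Acot2 by 1.30 ± 0.26, at least 2.36-fold. Peroxisomal genes were higher in 7 of 20 (13 higher adjusted over the list alone, camera adjusted p = 1.6e-13). So were omega-oxidation genes in 4 of 9 (5 higher adjusted over the list alone, camera adjusted p = 2.5e-09). In refed mice (n = 4 and 5) Pck1 was higher by 1.84 ± 0.27, Igfbp1 by 2.27 ± 0.59 and Ppp1r3g by 3.03 ± 0.80. Gluconeogenesis genes were higher in 11 of 20 (17 higher adjusted over the list alone, camera adjusted p = 4.8e-09, adjusted p = 0.11 with an estimated correlation). Beta-oxidation genes were higher in 12 of 18 (16 higher adjusted over the list alone, camera adjusted p = 3.3e-10, adjusted p = 0.13 with an estimated correlation). Cholesterol synthesis and lipogenesis genes were lower, with medians of -0.56 and -0.33 (camera adjusted p = 2.9e-07 and 9.4e-05). Both calls were lost with an estimated correlation (camera adjusted p = 0.33 for each). In fasted mice (n = 5 and 5) erythroid markers were higher in 1 of 7 (7 higher adjusted over the list alone, camera adjusted p = 2.2e-06, adjusted p = 0.55 with an estimated correlation). Ccl27a (-3.24 ± 0.81, -4.22 ± 0.67 and -3.10 ± 0.71), Tomm22 (-2.28 ± 0.28, -2.25 ± 0.23 and -2.43 ± 0.24), Bik (-2.36 ± 0.29, -2.13 ± 0.24 and -2.17 ± 0.25) and Stk3 (-2.10 ± 0.47, -2.41 ± 0.39 and -2.32 ± 0.41) were lower in LWT in all 3 states.

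The control line counts were 240 fed, 101 fasted and 1794 refed, and 305, 110 and 2121 with slide as a block. The fed count was 669 on the authors' value table, 153 in a fit of only the compared groups, 138 without LWT fed replicate 3 and 147 without LWT fed replicate 2. The fasted count was 43 in a fit of only the compared groups, 48 without the genes of chromosome 15, and 156 without LWT fasted replicate 5. The refed count was 118 in a fit of only the compared groups, 866 without LWT refed replicate 4 and 1132 without LWT refed replicate 5, and the share of called genes that were higher was 67.5% here and 39.2% on the authors' value table. Of the 29 genes that differed in all 3 states, 21 lay on chromosome 15, which holds Ppara.

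**Figure D3:**
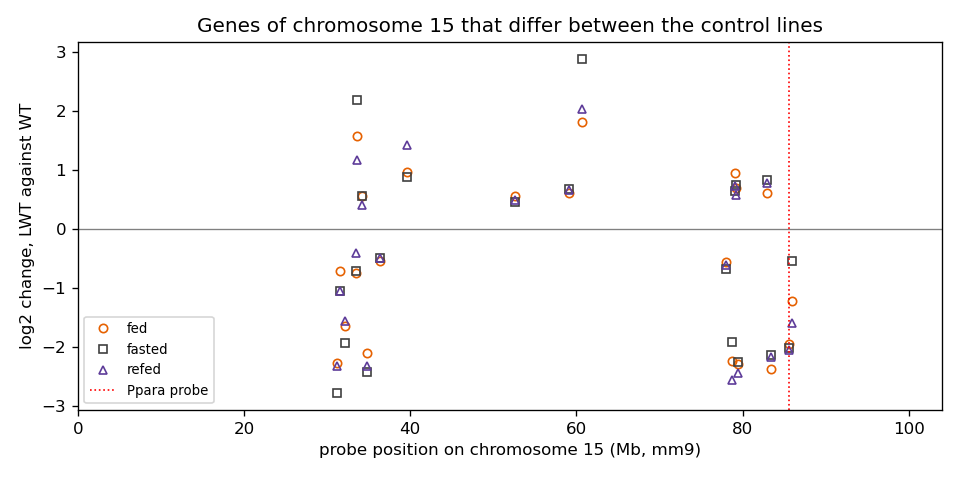
Log2 change of LWT against WT (vertical axis) by probe position on chromosome 15 in Mb of the mm9 build (horizontal axis) for the 21 genes of this chromosome that differed in all 3 feeding states, each drawn once per state, with the position of the Ppara probe as a dotted line. Stk3 lay in the first group of genes, at -2.10 fed, and Tomm22 and Bik near Ppara, at -2.28 and -2.36.

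A list can be called because its genes move together within groups. With the correlation estimated from the residuals, 56 of 338 list calls of the 22 planned contrasts stayed. They held beta-oxidation, peroxisomal and omega-oxidation genes in fed, fasted and refed LKO and fasted KO, chaperones in fasted KO, lipogenesis in the fasting of LWT, WT and LKO and in every refeeding, and none in fed or refed KO.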

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

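The tests of chromosome 15 for the control lines and of the Cyp4a14 rise were chosen only after the results were seen. All other tests in this part were planned.

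The effect of fasting differed between LKO and LWT for 1002 genes and between KO and WT for 5133. Cyp4a14 rose by 4.75 ± 0.52 more in LKO than in LWT, but less in KO than in WT. Its LKO difference holds a low fed signal in LKO, at most -2.24, and a fed signal higher in LWT than in WT. Acot3, which rose in WT and fell in KO, differed by -5.78 ± 0.60. The effect of the deletion itself differed between the whole body and the liver for 1611 genes in fed, 3553 in fasted and 4194 in refed mice, with Psat1 at 4.90 ± 0.76 in the fasted state. These are tests of the difference itself with limma.

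Probes without a gene name also responded. Of 10696 such probes above background, 846 were called in fasted LKO against LWT, 570 lower and 276 higher. In fasted KO against WT 2279 were called, 1419 lower and 860 higher. They enter no comparison by gene.

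Single arrays stood apart from their groups in 29 of 378 tests of the signal and list scores. The groups of 3 arrays, KO fasted, LKO fed and LWT fed, were too small for this test and were left out. Chance flags about 1 in 20 groups. Each number in the sentences that follow is the gap of that array to its nearest neighbour as a share of the range of its group, and a list score is the mean deviation of the members from their overall means.

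LKO refed replicate 1 stood apart in 6 lists. It was low for ketogenesis (0.749), urea cycle (0.758), sinusoidal endothelial markers (0.784), adipocyte markers (0.754) and pericentral markers (0.754), where its score was -1.01 and the others lay between -0.19 and 0.08. It was high for chaperones (0.948). LKO refed replicate 3 was high for lymphocyte markers (0.741) and LKO fasted replicate 3 low for CAR and PXR targets (0.836).

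In the LWT line, fasted replicate 5 was high for fatty acid uptake (0.896) and cholangiocyte markers (0.731), with a cholangiocyte score of 0.737 against -0.341 to -0.0511. Fasted replicate 1 was high for lipogenesis (0.759) and fasted replicate 3 low for peroxisomal genes (0.745). Refed replicate 2 was low for the integrated stress response (0.847), replicate 4 for NRF2 targets (0.889) and replicate 5 for the growth hormone axis (0.863).

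WT refed replicate 1 had a high 75th percentile of the signal (0.788), with 367 against 278 to 297, many spots well above background (0.767) and a low lipogenesis score (0.837). WT refed replicate 2 was high for glycolysis (0.75). WT fed replicate 1 had a high 75th percentile (0.843) and few outlier spots (0.9), and WT fed replicate 3 was high for female-biased genes (0.847). WT fasted replicate 5 was high for Ppara (0.821), at 7.07 against 6.76 to 6.82, and for NRF2 targets (0.735), and WT fasted replicate 4 was low for clock genes (0.724).

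In KO, fed replicate 2 had a high 75th percentile (0.772) and high adipocyte markers (0.802). Refed replicate 3 was high for lipoprotein genes (0.829) and Kupffer cell markers (0.793), with a Kupffer score of 0.578 against -0.247 to -0.0762.

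The 29 genes that differed between LWT and WT in all 3 states, with Stk3, Tomm22 and Bik among them, may in part reflect DNA of another strain on chromosome 15, which holds Ppara. Of these 72.4% lay on chromosome 15, against 4.08% of all placed genes (21 of 29 and 681 of 16696, Fisher's exact test p 1.5e-23), at mm9 positions 31254329 to 85967864. Slide does not account for them, since the slide-blocked change was 1.02 times the unblocked one (95% interval 0.996 to 1.03). A variant under the chosen probe alone cannot be told apart, because only 7 of the genes had another kept probe, at a median of 0.904 of the change (-0.16 to 1.07). The labels call both lines wild type and do not say whether LWT mice carry an altered Ppara locus, so how such DNA would come to be kept stays open. Only 9 of the genes on chromosome 15 lay within 10 Mb of the Ppara probe, and Stk3, at 34805255, was not among them. In KO against WT 10 of the 21 changed the same way in all 3 states, with Tomm22 at -2.35, -2.64 and -2.35. Their changes in KO need not come from the loss of PPARA. Stk3 changed by only 0.06, 0.35 and -0.12 there. The line is the difference the design names, and other effects of it stayed untested.

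The KO line had 183 such genes, changed by at least 1 log2 unit against WT in all 3 states and called in no LKO contrast, 107 lower and 76 higher, with 33 on chromosome 7 and 17 on chromosome 9. They may include DNA of another strain, as 56.7% had another of them within 2 Mb, against a median of 37.2% and a 95th percentile of 44.4% in random sets and 45.5% of the 212 genes changed in all states in LKO. Slide does not account for them, at a ratio of 1 (0.997 to 1.01). A variant under the probe cannot be told apart, since the other probes of 40 genes gave 0.516 of the change (0.247 to 0.892). An effect of PPARA outside the liver, which the design also names, stayed untested.

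Cyp4a14 rose on fasting in both deletions, by 9.41 ± 0.37 in LKO and 7.51 ± 0.37 in KO. PPARA left in some liver cells of LKO is not needed for such a rise, since the KO rise was 0.855 of the WT rise. The test used only KO and WT arrays, so it cannot exclude a share of such PPARA in the larger LKO rise. Signals at the floor do not account for the rises. The lowest fasted array lay 6.63 log2 units above the highest fed array of its genotype, and all fasted arrays were well above background. Signal of its close relatives alone is also argued against, since Cyp4a14 rose more on fasting than Cyp4a10, Cyp4a31 and Cyp4a32. The rise exceeded that of Cyp4a10 by 3.34 log2 units in LKO (95% interval 2.88 to 3.80) and 1.48 in KO (0.83 to 2.13). In deletion contrasts Cyp4a14 lay up to 2.32 from the nearest of them, in fed LKO where its signal was low, while in fasted LKO the changes of all 4 agreed within 0.69. A regulator other than PPARA may take part, which is a hypothesis raised by these same data and was not tested.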

How the results depend on the processing

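The fit without chromosome 15 was chosen after the data were seen, and the other alternatives were planned. Of 226 counts of called genes under the alternatives, 216 lay within 1.5 times the main count. Of 2755 values of named genes 41 lost and 2 gained a call and 0 reversed, and of 3463 list calls 267 were lost and 0 reversed. These totals leave out the single arrays and the estimated correlation. With the estimated correlation only 56 of 338 list calls stayed, the largest loss of any alternative, and leaving out 1 array at a time lost 44 gene calls and 248 list calls. Of the lost gene calls 25 came from fits of only the compared groups, and of the 267 lost list calls 69 came from the authors' value table and 57 from normexp.

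The authors' value table called 1033 genes in LKO against LWT fed, 1617 for the whole-body minus liver effect fasted and 669 in LWT against WT fed. The cause was not tested. A fit of only the compared groups takes the spread from those groups alone, with fewer arrays. It called 82 genes in LKO against LWT fed, 372 refed and 639 for the fasting response of LKO minus LWT. In LWT against WT it called 153 fed, 43 fasted and 118 refed. The number of arrays alone does not account for the losses. LWT against WT refed, with 4 and 5 arrays, fell from 1794 to 118. KO against WT fasted, with 3 and 5 arrays, gave 7646 against 7614. Whether the spread is equal in all groups, as the main fit assumes, was not tested. The fit without chromosome 15 left out 681 of 16696 placed genes, among them 21 that differed between LWT and WT in all 3 states. There LWT against WT fasted gave 48 against 101.

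Ppara in LKO against LWT fed was -0.66 in the fit of only the compared groups, with limma adjusted p from 5.6e-05 to 0.21 over the alternatives. Ppara in KO against WT refed lost its call with normexp (-0.24), no filter (-0.24), only the compared groups (-0.24) and the authors' table (-0.27), its limma adjusted p running from 0.00026 to 0.11. The cause was not tested.

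The correlation across genes of the deletion effects in fasted mice was 0.529, and 0.603 with normexp, 0.579 on the authors' table, 0.46 with no filter and 0.509 with slide as a block. In fed mice it was 0.277, and 0.174 with no filter. The cause was not tested. The genes that rose in fasted WT had a median of -0.08 in fasted LKO at a threshold of 0.58 and -0.35 at 2, both below the random lists, while the -0.07 at a threshold of 1 was not.

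The share of called genes that were higher depended on the scaling. In the fasting response of KO minus WT it was 38.9%, and 29% with normexp and 65.3% on the authors' table. It was 44% in fasted KO against WT and 59.2% on the authors' table, and 67.5% and 39.2% in LWT against WT refed. For the whole-body minus liver effect it was 60.4% and 40.2% fed, 45.5% and 53.6% fasted, and 60.4% and 46.3% refed, and 46% and 61% for the fasting response of LKO minus LWT. Other choices moved it too, as in LKO against LWT fed, with 37.3%, 22% in a fit of only the compared groups and 27.4% with slide as a block. The median of all genes moved by over 0.1 in 1 contrast on the authors' table, the fasting response of KO minus WT, and in 3 with no filter.

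Leaving out 1 array at a time gave 301 to 551 calls in LKO against LWT fed, 3788 to 4312 fasted and 824 to 2310 refed, and 3461 to 4180, 6389 to 7478 and 4450 to 5107 in KO against WT. Fasting gave 3060 to 3956 in LWT, 5875 to 6498 in WT, 4605 to 5351 in LKO and 5676 to 6992 in KO. Refeeding gave 5500 to 6032, 8064 to 8559, 7423 to 7782 and 6021 to 6958. The difference of fasting responses gave 657 to 1023 in LKO minus LWT and 4284 to 5095 in KO minus WT. The whole-body minus liver effect gave 1077 to 1804 fed, 2781 to 3545 fasted and 3511 to 4407 refed. LWT against WT gave 138 to 188, 72 to 156 and 866 to 2276. The lowest LKO fed count came without LWT fed replicate 2 and the lowest refed count without LWT refed replicate 4. Ppara ranged from -0.74 to -0.54 in LKO fed and from -0.31 to -0.21 in KO refed, and the correlations from 0.226 to 0.309 fed, 0.517 to 0.532 fasted and 0.039 to 0.109 refed. Leaving out 1 array of a group of 3 leaves a pair, whose spread the other groups inform.

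Replicate numbers did not pair the arrays, since correlations of the deviations of same-numbered arrays ran from -0.2 to 0.301. With replicate number as a block, as with slide, all 22 counts stayed within 1.5 times, and LKO against LWT fed gave 514. Of 338 list calls 13 were lost with the replicate block and 27 with the slide block. Signal near background limits values such as Fgf21 in fed mice, and group sizes of 3 limit the fed LKO contrast.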

Other observations

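The contrasts of refed with fed mice and the tests in the next paragraph were chosen only after the data were seen. A day of refeeding with glucose raised fat synthesis genes past their fed level in every genotype. Pnpla5 was higher than in fed mice by 4.96 ± 0.74 in LWT, 3.98 ± 0.65 in WT, 4.37 ± 0.71 in LKO and 5.01 ± 0.61, at least 8.68-fold in KO, and Pnpla3 by 3.88 ± 0.87, 3.57 ± 0.76, 4.42 ± 0.83 and 3.17 ± 0.72. Cyp4a14 also stayed above its fed level, by 6.13 ± 0.34 in WT, 5.24 ± 0.37 in LKO and 5.58 ± 0.32 in KO. Elovl3, a fatty acid elongase gene biased to males, changed in the same genotypes by -3.26 ± 0.57, -2.95 ± 0.62 and -2.31 ± 0.54.

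Lipogenesis genes were higher in 16 of 27 in LWT (17 higher adjusted over the list alone, camera adjusted p = 9.1e-22) and 19 in WT (19 higher adjusted over the list alone, camera adjusted p = 2.1e-20). They were higher in 19 in LKO (20 higher adjusted over the list alone, camera adjusted p = 1.3e-16) and 16 in KO (16 higher adjusted over the list alone, camera adjusted p = 7.8e-11, adjusted p = 0.27 with an estimated correlation). NRF2 targets were higher in 9 of 11 in LKO (9 higher adjusted over the list alone, camera adjusted p = 6.3e-09, adjusted p = 0.085 with an estimated correlation). Erythroid markers were lower in 7 of 7 in WT (7 lower adjusted over the list alone, camera adjusted p = 0.001, adjusted p = 0.47 with an estimated correlation). Refed against fed mice called 1681 genes in LWT, 4626 in WT, 4018 in LKO and 4569 in KO by limma.

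Other splits of the same arrays into groups of the same sizes were counted for each contrast, a planned test. For LKO against LWT fed the 10 splits are too few for a share under 0.05, with 501 genes called and 13 at most in another split. For each of the other contrasts the share of splits calling as many genes was under 0.05, with no correction over contrasts. For the differences of fasting responses and of deletion effects, the splits also mixed the genotype effects across groups. There they are no test of the difference itself, and no conclusion is drawn from them. The real count and the highest other were 4462 and 1518 in LKO against LWT fasted, 1747 and 1061 refed, 4317 and 3057 in KO against WT fed, 7614 and 3835 fasted, and 5123 and 2719 refed. For fasting they were 4138 and 1194 in LWT, 6571 and 5435 in WT, 5625 and 2127 in LKO and 7193 and 3091 in KO. For refeeding they were 6334 and 4672, 8712 and 5434, 7967 and 4420, and 7148 and 3453. For the differences of fasting responses they were 1002 and 1423 in LKO minus LWT and 5133 and 4914 in KO minus WT. The whole-body minus liver effect gave 1611 and 200 fed, 3553 and 3687 fasted, and 4194 and 1317 refed. LWT against WT gave 240 and 10 fed, 101 and 314 fasted, and 1794 and 1516 refed. In 3 contrasts 2 of 100 splits, the real one included, called as many genes. A split called 314 genes in fasted controls, about 3 times the real 101, and the cause was not tested.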
